A study of Mus musculus with 15 samples.

How the data were processed

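Bulk RNA was sequenced from syngeneic melanoma grafts, tumors grown from mouse melanoma cells in mice of the same inbred strain. The labels name 2 cell lines, D4M.3A.3 (parental) and D3UV2 (UV2, a line carrying putative neoantigens induced by UVB light), and inoculation of 1000000 cells per flank into female C57BL/6 mice aged 8 weeks. Therapy fell on days 8, 10 and 12 and tumors were taken on day 13. The 15 libraries form 5 groups of 3: parental isotype control antibody, parental anti-PD-1 (an antibody that blocks the T cell checkpoint receptor PD-1), parental triple therapy, UV2 isotype and UV2 anti-PD-1. The labels disagree on triple therapy: the sample characteristics list anti-PD-1, ablative fractional photothermolysis (a laser that removes small columns of skin) and imiquimod (a cream that activates the receptor Tlr7), whereas the treatment protocol gives isotype antibody in place of anti-PD-1. Which was given is unknown. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples.

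The deposited table holds TPM values (transcript abundance scaled to a fixed total) for 23420 gene symbols in 15 columns, computed by the authors, whose processing notes name Bowtie2 and RSEM without versions and the mouse builds mm10 and GRCm38. Each column sums to 1000000, so the values are relative to all transcripts of a library and the number of reads behind them is unknown. No counting interval is given for this reason, and a value listed at 0 can stand for no reads or for a failed estimate. All 15 columns were used, leaving 0 unused. Of the symbols, 4865 were 0 in every library, 2 occurred more than once, 27 had the form of a date, and 21751 matched a gene name of the GENCODE M21 annotation of GRCm38, from which positions were taken. Among the genes tested, 93.9% matched.

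Values were analysed as log2(TPM + 1) for the 13592 genes with a TPM of at least 1 in at least 3 libraries. One linear model with a coefficient per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend and robust set), leaving 10 residual degrees of freedom. The 6 comparisons of groups were UV2 against parental under isotype and under anti-PD-1, anti-PD-1 against isotype in each line, and triple therapy against isotype and against anti-PD-1 in the parental line. A contrast of contrasts tested whether the anti-PD-1 effect differed between the lines. All tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison.

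A set of 31 gene lists was fixed before the data were examined: T cell, cytotoxic effector, T cell checkpoint and exhaustion, regulatory T cell, NK cell, B and plasma cell, macrophage and monocyte, neutrophil, dendritic cell, interferon gamma response, type I interferon response, MHC class I presentation, MHC class II presentation, chemokines and inflammatory cytokines, Toll-like receptor signalling, melanocyte lineage, dedifferentiated melanoma, proliferation, fibroblast and extracellular matrix, endothelial, keratinocyte and hair follicle, skeletal muscle, adipocyte, erythrocyte, hypoxia and glycolysis, heat shock, wound and acute phase response, p53 and DNA damage response, immediate early genes, mitochondrially encoded, and cytosolic ribosomal protein. Older symbols in the table were matched where needed (Irg1 for Acod1, Chi3l3 for Chil3, Beta-s for Hbb-bs and others). None of the 13 mitochondrially encoded genes was in the table (0 of 13), which left 30 lists. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated, and with fry, each adjusted over the 30 lists of a comparison. Camera asks whether a list moved relative to the other genes, so its direction can differ from the sign of the list's mean. List levels (mean log2(TPM + 1) per library) were compared by exact permutation tests, which cannot go below p = 0.1 for 3 against 3.

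Genes to name were set by a rule fixed at the same time. Named were the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap and whose mean TPM reached 5 in the higher group, leaving out predicted and unnamed genes, mitochondrial genes and receptor or immunoglobulin segments. Also named were genes fixed in advance, among them Cd3e, Cd4, Cd8a, Foxp3, Gzmb, Prf1, Ifng, Pdcd1, Cd274, Cxcl9, B2m, Mitf, Sox10, Tyr, Tyrp1, Dct, Pmel and Mlana, up to 4 called members of each list with the smallest p (or 2 members where none was called), and, where fewer than 5 genes were called, the 5 with the smallest p.

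Alternatives fixed at the same time were a pseudocount of 0.1, no filter (18555 genes), a TPM minimum of 5 (11247 genes), median-of-ratios scaling, quantile normalization, a fit on the compared groups alone, the replicate number as a block, limma library weights, and leaving out each library. Replicate numbers did not pair libraries: the 30 same-number pairs of different groups had residual correlations from -0.54 to 0.47 with a median of -0.08, against a median of 0.04 for the 60 other pairs. Blocking on them was therefore tried only as an alternative. Covariates for the muscle and the keratinocyte list and gene-by-gene library weights were chosen after seeing the data. The fit was tested on simulated data (13592 genes) for UV2 isotype against parental isotype. Of genes changed by 1 and 2 (log2, 100 each), 53% and 89% were called. The 149 calls held 6 unchanged genes, 1 of 18 T cell list genes shifted by 1 and 0 of the wrong sign. These rates may differ in real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.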

Results

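Transcript abundance was measured in 15 bulk melanoma grafts, 3 in each of 5 groups. No read counts were given, so library depth is unknown. Between 12239 and 13993 genes reached 1 TPM per library. Correlations between libraries ranged from 0.820 to 0.990, and the first principal component held 40.2% of the variance of the tested genes. The most abundant transcript was Spp1, which encodes the secreted phosphoprotein osteopontin, in 11 libraries. The exceptions were parental triple therapy replicate 1 (Krt14, 11620.0 TPM), UV2 isotype replicate 1 (Eef1a1, 12500.0 TPM) and UV2 anti-PD-1 replicates 1 and 2 (Cd74, 12232 and 9997 TPM). Below, log2 fold changes carry their standard error and TPM means their standard deviation, with n = 3 libraries per group throughout. Positions are on GRCm38.

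The first comparison set UV2 against parental tumors under isotype antibody and asked how tumors of the UVB-derived line differed without therapy. Expression of Xlr, an X-linked lymphocyte-regulated gene, was higher in UV2 by 3.86 ± 0.25 on the log2 scale (44.5 ± 10.1 TPM against 2.10 ± 0.302 TPM, chromosome X, 53777118 to 53797706, adjusted p = 1.06e-05). Klhl4, a kelch-like gene, was higher by 3.38 ± 0.39 (19.9 ± 7.78 TPM against 0.913 ± 0.177 TPM, chromosome X, 114474333 to 114560829, adjusted p = 0.00443). Type I interferon response genes had the highest mean of the 30 lists, 1.59, and 16 of 31 rose over all genes and all 31 adjusted over the list alone. Akr1c18, which inactivates progesterone, fell by 4.92 (SE 0.76; 2.66 ± 1.81 TPM against 100.2 ± 18.3 TPM, chromosome 13, 4132615 to 4150654, adjusted p = 0.0214). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, fell by 4.14 (SE 0.82; 11.6 ± 8.06 TPM against 197 ± 49.0 TPM, chromosome 1, 150100031 to 150108227, adjusted p = 0.0376). The Y-linked genes Eif2s3y and Ddx3y were listed at 0 in every UV2 library against 12.6 ± 1.35 TPM and 9.57 ± 2.02 TPM in parental isotype tumors.

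In all, 176 of 13592 genes changed, 123 higher and 53 lower in UV2, and 2418 had an unadjusted p under 0.05. Also among the 10 highest were Ly6c2, a surface marker of inflammatory monocytes (2.75 ± 0.60, 339.7 ± 87.6 TPM against 61.2 ± 50.7 TPM, adjusted p = 0.0440), Ccdc3 (2.74 ± 0.53) and Serpina3g, an interferon-induced protease inhibitor (2.45 ± 0.40, 166 ± 62.2 TPM against 29.0 ± 10.1 TPM). The others were Nrgn (2.42 ± 0.37), BC147527 (2.40 ± 0.43), Phf11b (2.35 ± 0.42), Frzb, a secreted Wnt antagonist (2.32 ± 0.49), and Slfn1 (2.23 ± 0.43). The remaining lowest were Anxa8 (-3.65 ± 0.70, 14.7 ± 17.3 TPM against 123 ± 46.6 TPM), the small heat shock protein gene Hspb7 (-3.58 ± 0.61), the potassium channel gene Kcnk3 (-2.98 ± 0.56), the calcineurin inhibitor Rcan1 (-2.69 ± 0.54), Syt13 (-2.62 ± 0.47) and Efs (-2.35 ± 0.37). Groups that do not overlap were a condition for naming these 20 genes, met by 10% of genes by chance, so their separation adds no evidence. Scaling changed the balance of directions: median-of-ratios scaling gave 65 higher and 82 lower, and quantile normalization 72 higher and 70 lower. The count was 3, 3 and 458 without parental isotype replicates 1, 2 and 3, and 408, 3 and 61 without UV2 isotype replicates 1, 2 and 3. Of the named genes, Xlr and Klhl4 passed the test in each of these.

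Among type I interferon genes, Oasl1 (1.96 ± 0.32, 49.2 ± 10.0 TPM against 11.8 ± 1.05 TPM, chromosome 5, 114923240 to 114937915, adjusted p = 0.0214), Oas1a (2.19 ± 0.38), Oas1g (2.02 ± 0.36) and Trim30a (1.42 ± 0.24) rose. In this list 15 of the 31 did not pass over all genes. The type I interferon list lay at 6.45 ± 0.31 in UV2 isotype and 4.86 ± 0.10 in parental isotype libraries (mean log2 level, SD), with all 3 UV2 libraries above all 3 parental ones. Its camera adjusted p = 1.45e-29, its adjusted p = 0.389 with an estimated correlation, and its fry adjusted p = 0.0137. Of 26 interferon gamma response genes, 3 rose over all genes (Serpina3g; Socs1, a feedback inhibitor of cytokine signalling, 1.84 ± 0.36; and the transcription factor Irf8, 1.37 ± 0.29), with 18 higher and 1 lower adjusted over the list alone. Interferon gamma response genes averaged 1.26 (camera adjusted p = 7.98e-13, adjusted p = 0.389 with an estimated correlation). For MHC class II presentation, 1 of 12 rose (H2-DMb2, 1.66 ± 0.35, 14.8 ± 4.71 TPM against 3.91 ± 0.985 TPM) and 11 did so adjusted over the list alone. MHC class II presentation genes averaged 1.44 (camera adjusted p = 8.88e-09, adjusted p = 0.389 with an estimated correlation). MHC class I presentation had 0 of 22 past the test over all genes and 8 higher adjusted over the list alone, with a mean of 0.34 without UV2 isotype replicate 2. MHC class I presentation genes averaged 0.55 (camera adjusted p = 1.63e-05, adjusted p = 0.392 with an estimated correlation). Toll-like receptor signalling had 2 of 25 higher, Irf7, a driver of type I interferon production (2.23 ± 0.46, 556 ± 136 TPM against 118 ± 31.6 TPM), and Irf5 (1.28 ± 0.27), and 8 adjusted over the list alone. Toll-like receptor signalling genes averaged 0.53 (camera adjusted p = 1.32e-05, adjusted p = 0.392 with an estimated correlation). The list mean was 0.28 without UV2 isotype replicate 3.

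In UV2 isotype tumors 0 of 18 T cell genes passed over all genes by limma, 5 were higher adjusted over the list alone, and all 18 had positive log2 fold changes. T cell genes averaged 1.17 (camera adjusted p = 4.50e-08, adjusted p = 0.392 with an estimated correlation). Cd3e, a subunit of the T cell receptor complex, measured 1.19 ± 0.58 (adjusted p = 0.315) and Cd8a, the coreceptor of cytotoxic T cells, 1.24 ± 0.64 (adjusted p = 0.340). NK cell genes included 1 of 16 that rose, the chemokine gene Xcl1 (2.05 ± 0.39, 35.0 ± 9.27 TPM against 7.93 ± 3.28 TPM, adjusted p = 0.0313), and 9 adjusted over the list alone. NK cell genes averaged 1.08 (camera adjusted p = 2.43e-07, adjusted p = 0.392 with an estimated correlation). Of 22 macrophage and monocyte genes, Ly6c2 and the Fc receptor gene Fcgr1 (1.29 ± 0.27) rose, 10 adjusted over the list alone. Macrophage and monocyte genes averaged 0.77 (camera adjusted p = 2.01e-06, adjusted p = 0.389 with an estimated correlation). Among 20 dendritic cell genes Il12b rose (1.39 ± 0.30), 9 adjusted over the list alone. Dendritic cell genes averaged 0.90 (camera adjusted p = 6.55e-07, adjusted p = 0.389 with an estimated correlation). Among 8 regulatory T cell genes Il10 rose (1.61 ± 0.35), with 5 higher and 1 lower adjusted over the list alone. Regulatory T cell genes averaged 0.77 (camera adjusted p = 8.05e-04, adjusted p = 0.392 with an estimated correlation). Without UV2 isotype replicate 3 the means of the NK cell and regulatory T cell lists were 0.72 and 0.41. B and plasma cell and neutrophil genes did not pass camera. B and plasma cell genes averaged 0.68 (camera adjusted p = 0.0701, adjusted p = 0.524 with an estimated correlation). Neutrophil genes averaged 0.35 (camera adjusted p = 0.274, adjusted p = 0.865 with an estimated correlation). Both passed without parental isotype replicate 3 (means 1.39 and 0.78) and UV2 isotype replicate 1 (1.14 and 0.63), and B and plasma cell genes with a pseudocount of 0.1 (1.11), no filter (0.39) or the muscle covariate (0.75). Acta1, the muscle actin, was 229 TPM in parental isotype replicate 3 and 218.5 TPM in UV2 isotype replicate 3 and at most 5.91 TPM in the other isotype libraries. Erythrocyte genes had 0 of 5 positive, and the adjusted p was 0.0588 and 0.0606 without parental isotype replicates 1 and 3 and 0.0896 and 0.139 without UV2 isotype replicates 1 and 3. Erythrocyte genes averaged -1.34 (camera adjusted p = 0.0382, adjusted p = 0.395 with an estimated correlation). The adjusted p was 0.0739 with no filter and 0.0544 with the stricter filter.

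Genes of hypoxia and glycolysis and of cell division lay lower in UV2 isotype tumors. For hypoxia and glycolysis, 1 of 26 fell, Adm, which encodes the vasodilator adrenomedullin (-1.89 ± 0.41, 3.45 ± 1.54 TPM against 15.9 ± 8.20 TPM, adjusted p = 0.0440), and 18 were lower adjusted over the list alone. Hypoxia and glycolysis genes averaged -0.84 (camera adjusted p = 3.53e-09, adjusted p = 0.392 with an estimated correlation). The dedifferentiated melanoma list, with 4 of 17 positive, passed camera downward. Dedifferentiated melanoma genes averaged -0.53 (camera adjusted p = 0.0250, adjusted p = 0.524 with an estimated correlation). None of 29 proliferation genes passed the limma test over all genes or adjusted over the list alone. Proliferation genes averaged -0.30 (camera adjusted p = 0.00453, adjusted p = 0.664 with an estimated correlation). Without UV2 isotype replicate 2 the proliferation mean was -0.10 and that of the dedifferentiated melanoma list -0.26. In the p53 and DNA damage response list, which did not pass camera except without parental isotype replicate 2 (mean 0.23) or with either weights, Bbc3, a proapoptotic gene (1.45 ± 0.26), and the death receptor gene Fas (1.06 ± 0.19) rose, and among immediate early genes Nr4a1 fell (-2.30 ± 0.49). Genes of the p53 and DNA damage response averaged 0.17 (camera adjusted p = 0.124, adjusted p = 0.524 with an estimated correlation). Of the melanocyte genes fixed in advance, Sox10, Tyrp1, Dct, Pmel and Mlana were below the filter. Mitf, the lineage transcription factor, measured -0.36 ± 0.27 (6.80 ± 2.29 TPM against 9.09 ± 3.10 TPM, adjusted p = 0.544), and Tyr, the rate-limiting pigment enzyme, 0.24 ± 0.22 (adjusted p = 0.630). In total, 20 of 30 lists passed camera, 14 up and 6 down, and 0 passed with an estimated correlation.

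**Figure D1:**
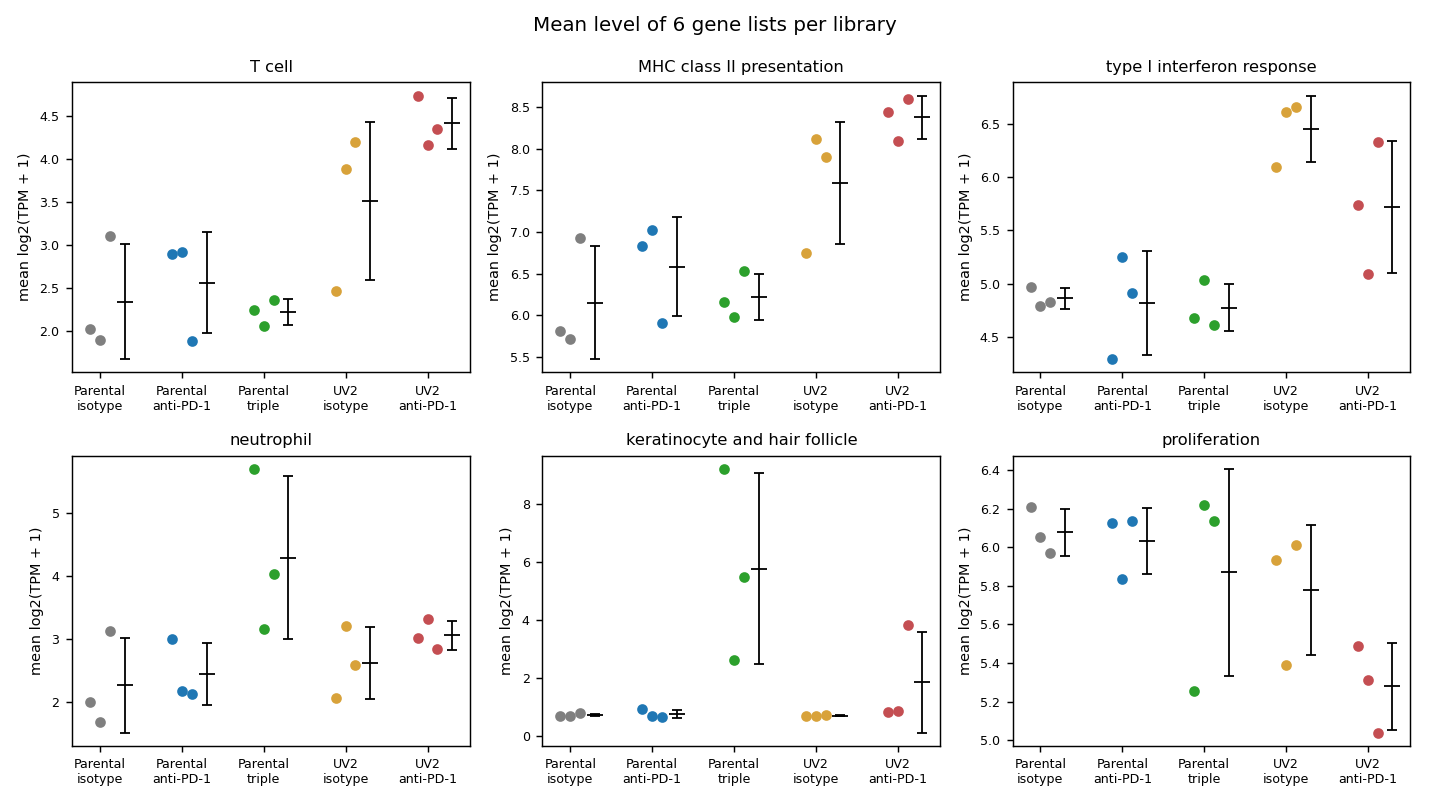
Mean log2(TPM + 1) of 6 gene lists (y axes) in each of the 15 libraries (points), by group (x axes), with the group mean and standard deviation. The type I interferon list averages 6.45 in UV2 isotype and 4.86 in parental isotype libraries, and the keratinocyte list spreads from 2.63 to 9.20 over the parental triple therapy libraries.

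Anti-PD-1 was next compared with isotype antibody in parental tumors, which asks how the parental line responded to PD-1 blockade. Genes of the interferon gamma response lay higher with anti-PD-1: all 26 measured genes had positive log2 fold changes with a mean of 0.72. The list level separated all 3 treated from all 3 isotype libraries. Such a separation has a probability of 0.1 by chance, and with 30 lists tested it adds no evidence. Gbp4, a guanylate-binding protein gene of cell-autonomous immunity, measured 1.48 ± 0.57 (58.7 ± 26.0 TPM against 18.9 ± 3.01 TPM, adjusted p = 1.00). The transcription factor gene Irf1 measured 0.63 ± 0.27 (158 ± 35.0 TPM against 100.2 ± 9.37 TPM, adjusted p = 1.00). Immediate early genes had 19 of 20 positive signs, with Junb at 0.79 ± 0.28 and Egr1 at 0.90 ± 0.38. T cell genes were close to their isotype level, with Cd3e at 10.2 ± 5.65 TPM against 8.63 ± 5.45 TPM, Cd8a at 11.7 ± 6.33 TPM against 9.16 ± 5.94 TPM and Ifng, the gene of interferon gamma, at 4.55 ± 0.982 TPM against 3.09 ± 2.05 TPM.

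No gene passed the limma test (0 of 13592, with 83 at an unadjusted p under 0.05), and the smallest adjusted p was 1. Nearest were Rmrp, listed at 0 in the isotype group and 1.80 ± 0.412 TPM with anti-PD-1, Atp6v0c, a subunit gene of the vacuolar proton pump (1.25 ± 0.31, 199.6 ± 43.3 TPM against 85.6 ± 32.7 TPM, chromosome 17, 24163866 to 24169702), Xrcc6bp1 (-0.73 ± 0.21), Higd1b (-1.29 ± 0.37) and Npff (0.73 ± 0.21). The interferon gamma list passed camera, as did immediate early genes, with 0 genes past the test over all genes or adjusted over the list alone in either. Interferon gamma response genes averaged 0.72 (camera adjusted p = 3.29e-17, adjusted p = 0.708 with an estimated correlation). Immediate early genes averaged 0.37 (camera adjusted p = 8.05e-07, adjusted p = 0.708 with an estimated correlation). The exact permutation p of both list levels was 0.1, the smallest that 3 against 3 allows. Skeletal muscle genes lay higher with anti-PD-1, with 20 of 20 positive. Skeletal muscle genes averaged 1.48 (camera adjusted p = 4.89e-07, adjusted p = 0.931 with an estimated correlation). Acta1 was 116 to 177 TPM in the treated libraries and 5.91, 3.91 and 229 TPM in the isotype libraries. Without parental isotype replicate 1 the muscle mean was 0.87 (adjusted p = 0.134), without replicate 2 0.87 (adjusted p = 0.232) and without replicate 3 2.71. It was 2.25 with a pseudocount of 0.1 and 2.51 with library weights, where immediate early genes averaged 0.60. The p53 and DNA damage response list had 23 of 26 positive signs, with Bbc3 at 0.50 ± 0.26 and the cell cycle inhibitor Cdkn1a at 0.30 ± 0.17. Genes of the p53 and DNA damage response averaged 0.22 (camera adjusted p = 0.00576, adjusted p = 0.708 with an estimated correlation). This list did not pass without parental isotype replicate 1 (mean 0.17, adjusted p = 0.228). In total 9 of 30 lists passed camera, 6 up and 3 down, 0 with an estimated correlation. The count was 3 without parental isotype replicate 1, 22 without parental isotype replicate 3 and 15 without parental anti-PD-1 replicate 3.

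Triple therapy was compared with isotype antibody in parental tumors to ask how the combined laser and cream treatment changed them. Keratin genes rose most. Krt6a and Krt16, keratins of wounded and hyperproliferative epidermis, were higher by 8.54 ± 1.23 (2172 ± 3368 TPM against 0.287 ± 0.249 TPM, chromosome 15, 101689910 to 101694307) and 8.48 ± 1.21 (2051 ± 3191 TPM against 0.200 ± 0.0794 TPM, chromosome 11, 100246091 to 100248902). Krt6b averaged 2272 ± 3569.7 TPM against a listed level of 0 (chromosome 15, 101676023 to 101680287). Each had an adjusted p of 0.0462, with all 3 treated libraries above all 3 isotype libraries. Keratinocyte and hair follicle genes as a group had a mean log2 fold change of 5.05, with 24 of 24 positive, 3 that rose over all genes and 21 adjusted over the list alone. Neither of the following genes passed the test. Cxcl1, a neutrophil-attracting chemokine, measured 2.19 ± 0.34 (9.08 ± 1.96 TPM against 1.34 ± 1.08 TPM, chromosome 5, 90891241 to 90893115, adjusted p = 0.0592). Irg1, which makes itaconate in activated macrophages, measured 2.38 ± 0.37 (32.6 ± 9.70 TPM against 5.32 ± 1.10 TPM, adjusted p = 0.0592).

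These 3 keratins were the only genes past the test among 13592, 3 higher and 0 lower, with 1714 at an unadjusted p under 0.05 and a median log2 fold change of all genes of 0.12. Their adjusted p was 0.335, 0.225 and 0.112 without parental isotype replicates 1, 2 and 3 and 0.240 without triple therapy replicate 3, each of which ended the calls. It was 0.0656 with median-of-ratios scaling and 0.0687 with quantile normalization. Leaving out triple therapy replicate 1 gave 5 calls and leaving out replicate 2 gave 257. The triple therapy libraries differed widely in keratinocyte transcripts: Krt14, the keratin of basal keratinocytes, was 11620.0, 85.7 and 845 TPM in replicates 1, 2 and 3 and at most 0.63 TPM in the other parental libraries. The summed transcripts of 4 Y-linked genes, which female hosts do not carry, were 1.08, 23.9 and 11.5 TPM in the same libraries and 20.4 to 29.8 TPM under isotype.

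The keratinocyte list passed camera, and its mean was 3.33 without triple therapy replicate 1. Keratinocyte and hair follicle genes averaged 5.05 (camera adjusted p = 3.90e-20, adjusted p = 0.704 with an estimated correlation). Of 20 neutrophil genes, 0 passed over all genes and 9 were higher adjusted over the list alone. Neutrophil genes averaged 2.03 (camera adjusted p = 1.49e-07, adjusted p = 0.704 with an estimated correlation). BC100530, a stefin gene of neutrophils, averaged 1183 ± 1823 TPM and was listed at 0 under isotype (adjusted p = 0.0913). Among 22 macrophage and monocyte genes 6 were higher adjusted over the list alone, with Chi3l3, a chitinase-like gene of alternatively activated macrophages, at 2.54 ± 0.50 and Nos2, the inducible nitric oxide synthase, at 2.18 ± 0.44. Macrophage and monocyte genes averaged 0.78 (camera adjusted p = 5.93e-05, adjusted p = 0.704 with an estimated correlation). Chemokines and inflammatory cytokines had 26 of 29 positive signs, 0 past the test over all genes and 5 adjusted over the list alone, with Tnf, the gene of tumor necrosis factor, at 1.14 ± 0.19 (11.4 ± 1.52 TPM against 4.62 ± 0.560 TPM, adjusted p = 0.0913). Chemokine and inflammatory cytokine genes averaged 0.98 (camera adjusted p = 1.52e-04, adjusted p = 0.704 with an estimated correlation). Fibroblast and extracellular matrix genes had 25 of 28 positive signs and 6 higher adjusted over the list alone. Fibroblast and extracellular matrix genes averaged 0.97 (camera adjusted p = 3.79e-05, adjusted p = 0.704 with an estimated correlation). The smooth muscle actin gene Acta2 measured 1.78 ± 0.48 and the collagenase gene Mmp13 2.38 ± 0.66. With the mean of the keratinocyte list as a covariate, chosen after seeing the data, the adjusted p was 0.149 for neutrophil (mean 0.56), 0.293 for macrophage (mean 0.41), 0.131 for chemokine (mean 0.49) and 0.187 for fibroblast genes (mean 0.56). Without triple therapy replicate 1 the neutrophil mean was 1.33 and the fibroblast mean 0.63.

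Interferon gamma response genes had 25 of 26 positive signs with triple therapy, 0 past the test over all genes and 4 higher adjusted over the list alone, with Serpina3g at 1.86 ± 0.40 and Irf1 at 0.90 ± 0.27. Interferon gamma response genes averaged 0.95 (camera adjusted p = 6.71e-07, adjusted p = 0.704 with an estimated correlation). Cd274, which encodes the PD-1 ligand PD-L1, measured 1.32 ± 0.42 (54.4 ± 13.9 TPM against 20.9 ± 3.90 TPM, adjusted p = 0.323). Toll-like receptor signalling had 24 of 25 positive signs, with the signalling inhibitor Irak3 at 1.43 ± 0.41. Toll-like receptor signalling genes averaged 0.54 (camera adjusted p = 8.21e-05, adjusted p = 0.704 with an estimated correlation). This call ended with the keratinocyte covariate (mean 0.25, adjusted p = 0.374). The T cell list passed camera downward with 0 genes past the test. T cell genes averaged -0.12 (camera adjusted p = 0.0424, adjusted p = 0.806 with an estimated correlation). The direction turned without parental isotype replicate 3 (mean 0.26) and with library weights (0.32) or gene-by-gene weights (0.28). The call ended without triple therapy replicate 2 (-0.041) or 3 (-0.19) and with median-of-ratios scaling (-0.23). The mean was -0.28 and -0.34 without parental isotype replicates 1 and 2, and -0.54 with quantile normalization. Single genes were Cd3e at 6.45 ± 1.68 TPM against 8.63 ± 5.45 TPM, Cd8a at 7.27 ± 1.27 TPM against 9.16 ± 5.94 TPM and Gzmb, the gene of the cytotoxic protease granzyme B, at 49.1 ± 24.4 TPM against 26.5 ± 11.9 TPM. Signs of mean and camera direction differed for cytotoxic effector, MHC class I presentation, MHC class II presentation, dedifferentiated melanoma, heat shock and erythrocyte genes, and the median and mean differed in sign for dendritic cell genes (median 0.01, mean -0.17). The dendritic cell call ended without parental isotype replicate 3 (0.054) or triple therapy replicate 2 (-0.037), with both weights, the stricter filter and median-of-ratios scaling. The mean was -0.26 and -0.29 without parental isotype replicates 1 and 2. Skeletal muscle genes lay higher in the treated group, with 19 of 20 positive, and did not pass without parental isotype replicate 1 (mean 1.14, adjusted p = 0.258) or 2 (mean 1.13, adjusted p = 0.357). Skeletal muscle genes averaged 1.75 (camera adjusted p = 0.0119, adjusted p = 0.806 with an estimated correlation). Without parental isotype replicate 3 the mean was 2.97, with library weights 3.14, with gene-by-gene weights 2.94 and with the keratinocyte covariate -0.091, where the direction turned. In total 17 of 30 lists passed camera, 11 up and 6 down, and 0 with an estimated correlation.

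**Figure D2:**
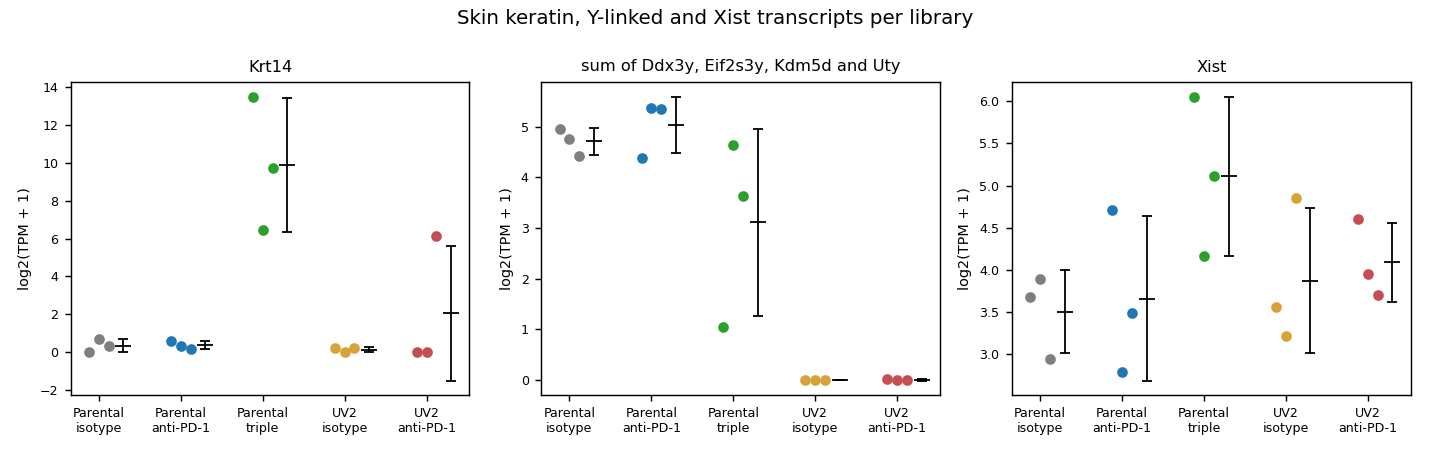
Krt14, the sum of 4 Y-linked genes and Xist (log2(TPM + 1), y axes) in each of the 15 libraries (points) by group (x axes). Krt14 spans 85.7 to 11620.0 TPM over the triple therapy libraries and is at most 69.5 TPM elsewhere, and the Y-linked sum is at most 0.02 TPM in UV2 libraries.

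Triple therapy was also compared with anti-PD-1 alone in parental tumors, the contrast that would isolate what laser and cream add if the triple arm held anti-PD-1. Keratinocyte genes again differed most, with a mean log2 fold change of 5.01 and 24 of 24 positive. Krt16 measured 8.54 ± 1.21 (2051 ± 3191 TPM against 0.153 ± 0.139 TPM), Krt6a 8.47 ± 1.23 and Krt6b 8.58 ± 1.25, each with an adjusted p of 0.0552. Krt14 measured 9.52 ± 1.62 (4184 ± 6452 TPM against 0.303 ± 0.196 TPM, chromosome 11, 100203162 to 100207548, adjusted p = 0.182). Fibroblast and extracellular matrix genes averaged 1.06, with the contractile gene Tagln at 2.10 ± 0.50 (136 ± 48.9 TPM against 38.8 ± 36.3 TPM, chromosome 9, 45929619 to 45936058, adjusted p = 0.377) and Acta2 at 1.95 ± 0.48. Among T cell genes 16 of 18 were negative, with a mean of -0.34 and the checkpoint receptor gene Tigit at -1.43 ± 0.55 (4.24 ± 2.06 TPM against 13.2 ± 5.63 TPM).

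No gene passed the limma test (0 of 13592, with 1411 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0552. The count was 3 without triple therapy replicate 1 and 195 without replicate 2. Of 24 keratinocyte genes, 21 were higher adjusted over the list alone, with a mean of 3.29 without triple therapy replicate 1. Keratinocyte and hair follicle genes averaged 5.01 (camera adjusted p = 5.64e-25, adjusted p = 0.764 with an estimated correlation). Fibroblast genes had 5 of 28 higher adjusted over the list alone, neutrophil genes 7 of 20 and macrophage genes 1 of 22. Fibroblast and extracellular matrix genes averaged 1.06 (camera adjusted p = 1.17e-07, adjusted p = 0.764 with an estimated correlation). Neutrophil genes averaged 1.86 (camera adjusted p = 5.91e-08, adjusted p = 0.764 with an estimated correlation). The macrophage and monocyte list averaged 0.67 (camera adjusted p = 4.42e-05, adjusted p = 0.764 with an estimated correlation). Endothelial genes had 17 of 19 positive signs and 0 past the test adjusted either way, with the vessel genes Emcn at 1.32 ± 0.46 and Egfl7 at 1.05 ± 0.42. Endothelial genes averaged 0.83 (camera adjusted p = 2.08e-04, adjusted p = 0.764 with an estimated correlation). With the keratinocyte covariate the neutrophil mean was 0.40 (adjusted p = 0.293), the macrophage mean 0.29 (adjusted p = 0.352), the fibroblast mean 0.65 and the endothelial mean 0.15, with camera then placing endothelial genes down (adjusted p = 0.809). Without triple therapy replicate 1 the neutrophil mean was 1.15 and the endothelial mean 0.37. The T cell list passed camera downward and did not pass without parental anti-PD-1 replicate 2 (mean -0.17, adjusted p = 0.226) or triple therapy replicate 2 (adjusted p = 0.0722). T cell genes averaged -0.34 (camera adjusted p = 0.00446, adjusted p = 0.764 with an estimated correlation). The T cell mean was -0.18 without parental anti-PD-1 replicate 1, -0.68 without replicate 3 and -0.64 with quantile normalization. Its sign turned with library weights (0.18, adjusted p = 0.876) and gene-by-gene weights (0.10, adjusted p = 0.710), where the list did not pass. Tlr7, the receptor that imiquimod activates, measured 1.08 ± 0.37 (19.2 ± 8.57 TPM against 8.19 ± 2.15 TPM, adjusted p = 0.397). In total 14 of 30 lists passed camera, 8 up and 6 down, and 0 with an estimated correlation.

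Anti-PD-1 was then compared with isotype antibody in UV2 tumors, which asks how the line with UVB-induced putative neoantigens responded. The 2 genes past the test were both of sterol synthesis: Idi1, the isopentenyl diphosphate isomerase, fell by 1.72 (SE 0.23, 18.7 ± 1.65 TPM against 64.5 ± 13.6 TPM, chromosome 13, 8885501 to 8892451). Sqle, the squalene epoxidase, fell by 1.60 (SE 0.21, 20.2 ± 3.60 TPM against 64.0 ± 15.6 TPM, chromosome 15, 59315077 to 59331192). Each had an adjusted p of 0.0336, with all 3 treated libraries below all 3 isotype libraries. T cell genes lay higher, with 18 of 18 positive and a mean of 0.90, as did MHC class II presentation genes with a mean of 0.79. Cd3e measured 1.21 ± 0.58 (adjusted p = 0.557), Ifng 1.46 ± 0.51 (26.4 ± 6.62 TPM against 10.2 ± 6.09 TPM, adjusted p = 0.542) and Pdcd1, the gene of PD-1, 1.35 ± 0.65 (adjusted p = 0.555). Type I interferon response and proliferation genes lay lower, with 0 of 31 and 0 of 29 positive.

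Idi1 and Sqle were the genes past the test (0 higher, 2 lower), with 1245 at an unadjusted p under 0.05 and a median of all genes of -0.11. The next 3 also act in sterol synthesis: Cyp51 (-1.39 ± 0.20, adjusted p = 0.0560), Hmgcs1 (-1.56 ± 0.24, adjusted p = 0.0632) and Sc4mol (-1.13 ± 0.20, adjusted p = 0.232). Both calls ended without UV2 isotype replicate 1 (adjusted p = 0.244 for both), UV2 isotype replicate 2 (0.166 and 0.0845) and UV2 anti-PD-1 replicates 1 (0.242), 2 (0.0876) and 3 (0.265). Without UV2 isotype replicate 3 the adjusted p of Sqle was 0.0679. The Idi1 call ended with median-of-ratios scaling (adjusted p = 0.141), and both calls ended with quantile normalization (0.189 and 0.0549).

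**Figure D3:**
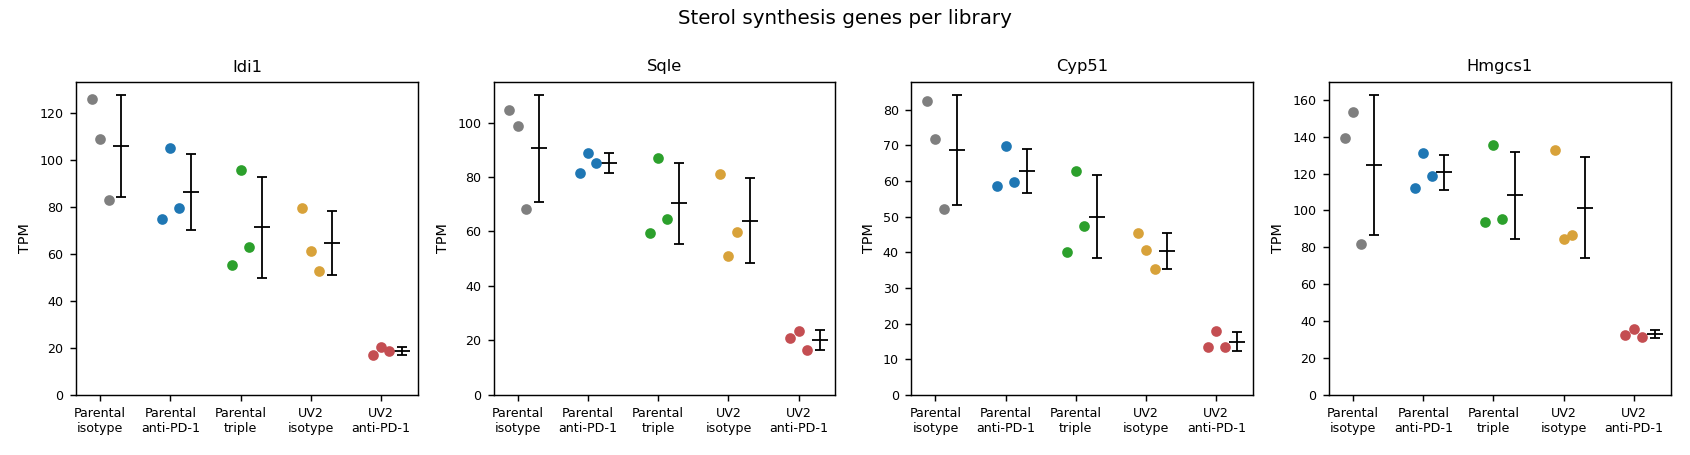
TPM (y axes) of Idi1, Sqle, Cyp51 and Hmgcs1 in each of the 15 libraries (points) by group (x axes), with the group mean and standard deviation. In UV2 tumors the means of Idi1 are 64.5 TPM under isotype and 18.7 TPM with anti-PD-1.

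In the lists that follow 0 members passed the limma test, over all genes or adjusted over the list alone. T cell genes passed camera, as did cytotoxic effector genes with 20 of 21 positive, among them Gzmk, a granzyme (1.74 ± 0.59, 10.6 ± 4.12 TPM against 2.95 ± 2.93 TPM). T cell genes averaged 0.90 (camera adjusted p = 9.50e-10, adjusted p = 0.364 with an estimated correlation). Cytotoxic effector genes averaged 0.87 (camera adjusted p = 6.36e-08, adjusted p = 0.364 with an estimated correlation). Checkpoint and exhaustion genes had 17 of 18 positive, with the inhibitory receptor gene Lag3 at 1.30 ± 0.51 (74.6 ± 12.1 TPM against 36.1 ± 22.7 TPM). T cell checkpoint and exhaustion genes averaged 0.70 (camera adjusted p = 1.74e-08, adjusted p = 0.364 with an estimated correlation). Cd74, the invariant chain of MHC class II, measured 1.32 ± 0.58 (11615 ± 1414 TPM against 5572 ± 3529 TPM) and H2-Ab1 1.39 ± 0.61, in a list with 11 of 12 positive. MHC class II presentation genes averaged 0.79 (camera adjusted p = 3.79e-06, adjusted p = 0.392 with an estimated correlation). Macrophage and monocyte genes had 18 of 22 positive, with the lysozyme gene Lyz2 at 0.79 ± 0.26. The macrophage and monocyte list averaged 0.43 (camera adjusted p = 2.07e-06, adjusted p = 0.364 with an estimated correlation). Without UV2 isotype replicate 1 these 5 means were 0.38, 0.38, 0.26, 0.37 and 0.27 in the same order. The exact permutation p of the T cell list level was 0.2 (4.41 ± 0.29 against 3.51 ± 0.92).

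Type I interferon response genes passed camera downward in UV2 tumors with anti-PD-1, with a mean of -0.42 without UV2 anti-PD-1 replicate 2. Mx2, annotated as a polymorphic pseudogene, measured -1.01 ± 0.29 (5.80 ± 2.41 TPM against 12.3 ± 1.96 TPM) and Isg20 -0.72 ± 0.23. Genes of the type I interferon response averaged -0.73 (camera adjusted p = 8.61e-09, adjusted p = 0.392 with an estimated correlation). Proliferation genes did likewise, with the replication gene Mcm5 at -0.60 ± 0.16 and the cyclin gene Ccnb2 at -0.61 ± 0.20. Proliferation genes averaged -0.50 (camera adjusted p = 6.36e-08, adjusted p = 0.392 with an estimated correlation). Wound and acute phase response genes had 23 of 23 positive, with the interleukin-33 receptor gene Il1rl1 at 1.43 ± 0.49 and the acute phase gene Saa3 at 2.13 ± 0.91. Wound and acute phase response genes averaged 0.90 (camera adjusted p = 3.77e-08, adjusted p = 0.364 with an estimated correlation). The wound list mean was 0.55 without UV2 isotype replicate 1. Neutrophil genes had 16 of 20 positive, with a mean of 0.17 without UV2 isotype replicate 1 and 0.74 without replicate 2. Neutrophil genes averaged 0.45 (camera adjusted p = 4.96e-04, adjusted p = 0.392 with an estimated correlation). Markers of other tissues lay higher too: adipocyte genes had 13 of 14 positive and a mean of 1.07 without UV2 anti-PD-1 replicate 1, and skeletal muscle genes 20 of 20. Adipocyte genes averaged 1.61 (camera adjusted p = 3.68e-05, adjusted p = 0.392 with an estimated correlation). Skeletal muscle genes averaged 1.65 (camera adjusted p = 1.20e-06, adjusted p = 0.392 with an estimated correlation). With library weights the means of neutrophil, keratinocyte, muscle and wound genes were 0.91, 0.37, 2.94 and 1.49. The neutrophil mean was 0.14 with the muscle and 0.11 with the keratinocyte covariate. The muscle mean was 1.00, 1.02 and 2.93 without UV2 isotype replicates 1, 2 and 3 and 3.04, 0.84 and 1.06 without UV2 anti-PD-1 replicates 1, 2 and 3. Keratinocyte genes had 23 of 24 positive, and without UV2 anti-PD-1 replicate 3, where Krt14 was 69.5 TPM, their mean was 0.14 (adjusted p = 0.627). Keratinocyte and hair follicle genes averaged 1.14 (camera adjusted p = 4.86e-05, adjusted p = 0.473 with an estimated correlation). In total 26 of 30 lists passed camera, 24 up and 2 down, 0 with an estimated correlation, and the count was 16 without UV2 isotype replicate 1.

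UV2 and parental tumors were also compared under anti-PD-1, which asks how treated tumors differed. Gbp1, a guanylate-binding protein gene, was higher by 4.46 ± 0.98 (89.5 ± 65.1 TPM against 2.27 ± 1.18 TPM, adjusted p = 0.0157). Batf3, the transcription factor of cross-presenting dendritic cells, was higher by 3.42 ± 0.63 (54.8 ± 22.6 TPM against 4.40 ± 2.70 TPM, chromosome 1, 191097847 to 191108945, adjusted p = 0.0110). Cd8b1, a subunit of the CD8 coreceptor, was higher by 2.83 ± 0.67 (77.8 ± 17.1 TPM against 10.8 ± 5.02 TPM, chromosome 6, 71322788 to 71337494, adjusted p = 0.0181). Of 18 T cell genes 14 rose, and of 12 MHC class II presentation genes 10 rose. Of 29 proliferation genes 15 fell, and of 26 hypoxia and glycolysis genes 16 fell and 1 rose.

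In all, 3586 of 13592 genes changed, 1265 higher and 2321 lower in UV2, with 6130 at an unadjusted p under 0.05 and a median of all genes of -0.21. With median-of-ratios scaling, which moved that median to 0.03, the split was 1951 higher and 1793 lower. The count was 1213 and 9 without parental anti-PD-1 replicates 1 and 3, 1475 and 9 without UV2 anti-PD-1 replicates 2 and 3, and 2225 with the keratinocyte covariate. Xlr (3.26 ± 0.25, 27.0 ± 3.18 TPM against 2.01 ± 1.01 TPM, adjusted p = 8.36e-05) was the named gene that passed in each of these. Others of the 10 highest were Retnla, a marker of alternatively activated macrophages (3.65 ± 1.10), Clec4b1 (3.29 ± 0.75), the NK receptor gene Klra17 (3.23 ± 0.86), Ptprcap (3.09 ± 0.61), Fam26f (2.91 ± 0.53) and the cell cycle inhibitor Cdkn1c (2.84 ± 0.89). Klra33, Tgoln2, Eif2s3y and Ddx3y were listed at 0 in UV2 against 22.1 ± 10.1 TPM, 18.3 ± 10.2 TPM, 16.2 ± 6.03 TPM and 12.5 ± 3.91 TPM. The remaining lowest were Akr1c18 (-3.77 ± 0.76, 6.14 ± 4.53 TPM against 90.6 ± 48.7 TPM), the BMP antagonist Grem1 (-3.42 ± 0.92, 47.2 ± 38.1 TPM against 432 ± 243 TPM), the activin subunit Inhba (-3.41 ± 0.85), Ptgs2 (-3.40 ± 0.82), the Wnt antagonist Dkk2 (-3.39 ± 0.85) and Dmp1 (-3.29 ± 0.96). As above, groups that do not overlap were a condition for naming these genes.

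Of the T cell genes, 16 of 18 were higher adjusted over the list alone, including Cd3e (2.21 ± 0.58, 46.9 ± 17.1 TPM against 10.2 ± 5.65 TPM, adjusted p = 0.0241), Cd2 (2.37 ± 0.48) and the T cell kinase gene Lck (2.23 ± 0.49). T cell genes averaged 1.85 (camera adjusted p = 1.34e-10, adjusted p = 0.316 with an estimated correlation). Cd8a rose by 2.10 ± 0.64 (adjusted p = 0.0359), Foxp3, the regulatory T cell factor, by 1.00 ± 0.34 (adjusted p = 0.0464) and Pdcd1 by 2.26 ± 0.65 (adjusted p = 0.0292). Cd4 measured 0.66 ± 0.52 and Cd274 0.18 ± 0.42 (adjusted p = 0.328 and 0.749). For cytotoxic effector genes 13 of 21 rose, 14 adjusted over the list alone. Cytotoxic effector genes averaged 1.29 (camera adjusted p = 4.31e-08, adjusted p = 0.316 with an estimated correlation). Among them, Ifng rose by 2.29 ± 0.51 (26.4 ± 6.62 TPM against 4.55 ± 0.982 TPM, adjusted p = 0.0160), Gzmb by 1.84 ± 0.57 and Nkg7, a granule protein gene, by 2.68 ± 0.57, with Prf1, the pore-forming perforin, at 1.21 ± 0.54 (adjusted p = 0.103). NK cell genes had 12 of 16 higher and 13 adjusted over the list alone, with the activating receptor gene Klrk1 at 2.03 ± 0.47. NK cell genes had a median of 1.61 (camera adjusted p = 1.48e-08, adjusted p = 0.316 with an estimated correlation). Checkpoint and exhaustion genes had 10 of 18 higher and 1 lower, counts that were the same adjusted over the list alone: Lag3 rose by 2.24 ± 0.51, Ctla4 by 2.04 ± 0.44, and the orphan nuclear receptor gene Nr4a2 measured -2.80 ± 0.63. T cell checkpoint and exhaustion genes averaged 1.03 (camera adjusted p = 1.55e-06, adjusted p = 0.316 with an estimated correlation). Regulatory T cell genes had 4 of 8 higher and 6 adjusted over the list alone, with Il10 at 2.09 ± 0.35. Regulatory T cell genes averaged 1.10 (camera adjusted p = 2.31e-04, adjusted p = 0.316 with an estimated correlation).

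Dendritic cell genes had 11 of 20 higher in UV2, with 13 higher and 1 lower adjusted over the list alone. Dendritic cell genes averaged 1.13 (camera adjusted p = 6.49e-07, adjusted p = 0.316 with an estimated correlation). Xcr1, a chemokine receptor of cross-presenting dendritic cells, rose by 1.53 ± 0.29. Macrophage and monocyte genes had 12 of 22 higher and 14 adjusted over the list alone, with the complement gene C1qb at 1.80 ± 0.30 (3558 ± 592 TPM against 1041 ± 279 TPM). Macrophage and monocyte genes averaged 1.09 (camera adjusted p = 2.02e-08, adjusted p = 0.316 with an estimated correlation). MHC class II presentation genes had 12 of 12 higher adjusted over the list alone, with H2-DMa at 2.14 ± 0.42 (307 ± 81.1 TPM against 69.3 ± 20.1 TPM). MHC class II presentation genes averaged 1.79 (camera adjusted p = 2.02e-08, adjusted p = 0.316 with an estimated correlation). Type I interferon response genes had 13 of 31 higher and 15 adjusted over the list alone, with Ifi27l2a at 2.31 ± 0.46, and a mean of 0.59 without UV2 anti-PD-1 replicate 3. Type I interferon response genes averaged 0.90 (camera adjusted p = 1.47e-09, adjusted p = 0.382 with an estimated correlation). Interferon gamma response genes had 5 of 26 higher and 1 lower, with 7 higher and 1 lower adjusted over the list alone. Interferon gamma response genes averaged 0.85 (camera adjusted p = 1.93e-06, adjusted p = 0.497 with an estimated correlation). With library weights the mean was 0.19 and the call ended (adjusted p = 0.123), and with gene-by-gene weights it was 0.34. These weights gave type I interferon genes means of 0.38 and 0.49. Chemokines and inflammatory cytokines had 8 of 29 higher and 1 lower, with 9 higher and 1 lower adjusted over the list alone. Chemokine and inflammatory cytokine genes averaged 0.89 (camera adjusted p = 1.33e-05, adjusted p = 0.316 with an estimated correlation). B and plasma cell genes had 1 of 6 higher over all genes and adjusted over the list alone, Cd79b of the B cell receptor (2.20 ± 0.57). B and plasma cell genes averaged 1.12 (camera adjusted p = 0.0129, adjusted p = 0.497 with an estimated correlation). The list had a mean of 0.69 without parental anti-PD-1 replicate 3 and an adjusted p of 0.0666 with median-of-ratios scaling. Cytosolic ribosomal protein genes had 4 of 34 higher and 2 adjusted over the list alone, with a mean of 0.57 with median-of-ratios scaling and 0.05 with quantile normalization (adjusted p = 0.371). Cytosolic ribosomal protein genes averaged 0.30 (camera adjusted p = 6.64e-07, adjusted p = 0.541 with an estimated correlation).

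Proliferation genes were lower in UV2, 22 of 29 adjusted over the list alone, including the mitotic transcription factor Foxm1 (-1.58 ± 0.42, 23.6 ± 8.19 TPM against 69.8 ± 9.69 TPM, adjusted p = 0.0250) and the cyclin gene Ccnb1 (-1.29 ± 0.36). Proliferation genes averaged -0.75 (camera adjusted p = 3.90e-05, adjusted p = 0.559 with an estimated correlation). With median-of-ratios scaling the mean was -0.49. Hypoxia and glycolysis genes had 16 of 26 lower and 1 higher, with 18 lower and 1 higher adjusted over the list alone. Hypoxia and glycolysis genes averaged -0.88 (camera adjusted p = 3.16e-04, adjusted p = 0.558 with an estimated correlation). The oxygen sensor Egln3 measured -1.85 ± 0.34 and Vegfa, the vascular growth factor, -1.55 ± 0.33. Dedifferentiated melanoma genes had 7 of 17 lower and 9 adjusted over the list alone, with the repressor gene Zeb1 at -1.58 ± 0.39. Dedifferentiated melanoma genes averaged -0.82 (camera adjusted p = 0.0367, adjusted p = 0.559 with an estimated correlation). The call ended without UV2 anti-PD-1 replicate 3 (mean -0.52, adjusted p = 0.0588). It also ended with library weights (mean -0.60, adjusted p = 0.113) and gene-by-gene weights (mean -0.64, adjusted p = 0.0756). Among lists that did not pass camera, melanocyte lineage had 2 higher (Rab32 and Rab27a) and 2 lower (Met and Pax3) of 12, the same counts adjusted over the list alone and a camera direction upward against a negative mean. Melanocyte lineage genes averaged -0.08 (camera adjusted p = 0.363, adjusted p = 0.700 with an estimated correlation). Heat shock had 6 lower of 20 and 8 adjusted over the list alone, including the chaperone Hsp90ab1 at -0.71 ± 0.16. Heat shock genes averaged -0.48 (camera adjusted p = 0.0502, adjusted p = 0.640 with an estimated correlation). Endothelial had 2 lower of 19 and 0 adjusted over the list alone, the vascular receptor genes Flt1 (-1.40 ± 0.43) and Eng. Endothelial genes averaged 0.22 (camera adjusted p = 0.0996, adjusted p = 0.721 with an estimated correlation). Heat shock passed without parental anti-PD-1 replicates 2 (-0.66) and 3 (-0.46) and UV2 anti-PD-1 replicate 2 (-0.57). Endothelial passed without parental replicate 1 (0.60) and UV2 replicate 3 (0.54). Wound and acute phase response genes had a negative median (-0.71) and mean but an upward camera direction. Wound and acute phase response genes averaged -0.27 (camera adjusted p = 0.861, adjusted p = 0.948 with an estimated correlation). In total 20 of 30 lists passed camera, 17 up and 3 down, and 0 with an estimated correlation.

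**Figure D4:**
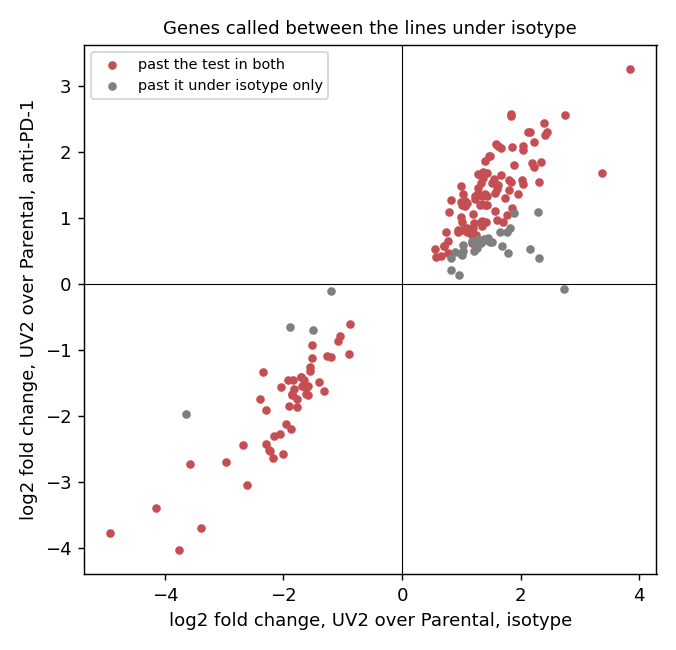
Log2 fold change of UV2 against parental tumors under isotype antibody (x axis) and under anti-PD-1 (y axis) for the 176 genes called under isotype (points). Red points passed the test in both comparisons (94 higher and 49 lower) and grey points under isotype alone, and 175 of 176 have the same sign in both.

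The difference between the anti-PD-1 effects of the lines was tested as an interaction, which asks whether UV2 and parental tumors responded differently. T cell genes had 18 of 18 positive differences and a mean of 0.68. Cytotoxic effector genes had a mean of 0.66, but 0.16 without UV2 isotype replicate 1, where the list did not pass (adjusted p = 0.0950). It was 0.36, 0.39 and 1.07 without parental isotype replicate 3, parental anti-PD-1 replicate 2 and UV2 isotype replicate 3. Among the smallest p-values were 4 sterol synthesis genes: Sqle at -1.54 ± 0.30, Hmgcs1 at -1.56 ± 0.34, Idi1 at -1.44 ± 0.32 and Cyp51 at -1.28 ± 0.29 (adjusted p = 0.800 for each). Cd3e differed by 1.02 ± 0.83, Cd8a by 0.85 ± 0.91 and Ifng by 0.92 ± 0.72 (adjusted p = 0.800 for each).

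No gene passed the limma test (0 of 13592, with 404 at an unadjusted p under 0.05), and the median difference of all genes was -0.16. Of 30 lists 19 passed camera, 17 up and 2 down, and 0 with an estimated correlation. T cell, wound and acute phase response and erythrocyte genes were among the upward ones, and type I interferon response and proliferation genes were the downward ones. T cell genes averaged 0.68 (camera adjusted p = 3.85e-06, adjusted p = 0.575 with an estimated correlation). Wound and acute phase response genes averaged 0.74 (camera adjusted p = 1.08e-05, adjusted p = 0.575 with an estimated correlation). Erythrocyte genes averaged 2.25 (camera adjusted p = 0.00115, adjusted p = 0.575 with an estimated correlation). Genes of the type I interferon response averaged -0.69 (camera adjusted p = 3.79e-05, adjusted p = 0.575 with an estimated correlation). Proliferation genes averaged -0.46 (camera adjusted p = 7.85e-04, adjusted p = 0.599 with an estimated correlation). In these lists 0 genes passed over all genes and, of the erythrocyte list, 1 of 5 adjusted over the list alone. The T cell mean was 0.30 without parental isotype replicate 3, 0.34 without parental anti-PD-1 replicate 3 and 0.16 without UV2 isotype replicate 1. The erythrocyte mean was 3.39 with a pseudocount of 0.1, 1.45 with no filter and 1.41 without UV2 anti-PD-1 replicate 1, and the type I interferon mean was -0.38 (adjusted p = 0.0546) without UV2 anti-PD-1 replicate 2 and -0.61 (adjusted p = 0.127) without UV2 isotype replicate 2. For wound genes the mean was 0.49, 1.20, 0.35 and 0.39 without parental isotype replicate 3, parental anti-PD-1 replicates 1 and 2 and UV2 isotype replicate 1. Proliferation genes averaged -0.25 with median-of-ratios scaling and -0.30 with the keratinocyte covariate, and wound genes 1.29 with library weights. The count of lists was 11 with median-of-ratios scaling, 11 with quantile normalization and 12 without UV2 isotype replicate 1.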

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

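The differences below come from the interaction of line and antibody, a test fixed in advance. Each value is the mean log2 difference between the anti-PD-1 effect in UV2 and that in parental tumors, for a list that passed camera at the preset correlation. Positive differences were those of T cell (0.68), cytotoxic effector (0.66), T cell checkpoint and exhaustion (0.45), NK cell (0.42), regulatory T cell (0.34), macrophage and monocyte (0.32), neutrophil (0.27), dendritic cell (0.23), MHC class II presentation (0.36), chemokines and inflammatory cytokines (0.40), fibroblast and extracellular matrix (0.38), endothelial (0.23), keratinocyte and hair follicle (1.10), adipocyte (1.22), erythrocyte (2.25), wound and acute phase response (0.74) and cytosolic ribosomal protein (0.066). Type I interferon response (-0.69) and proliferation (-0.46) had negative ones. For ribosomal protein genes the effect itself was -0.031 in UV2 and -0.098 in parental tumors. With the correlation between genes estimated, 0 of the 30 lists passed, and limma called 0 genes with 404 at an unadjusted p under 0.05.

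Over 23 alternatives (22 for keratinocyte genes) 5 of these lists passed camera in each, with means of 0.16 to 1.02 (T cell), 0.13 to 0.52 (macrophage), 1.41 to 3.39 (erythrocyte), 0.35 to 1.29 (wound) and -0.65 to -0.25 (proliferation). The others passed in fewer, given after each name, with means of 0.16 to 1.07 (cytotoxic effector, 22), 0.012 to 0.74 (checkpoint, 22), -0.0073 to 0.79 (NK cell, 21), 0.030 to 0.69 (regulatory T cell, 12), -0.15 to 0.65 (neutrophil, 18), -0.0022 to 0.45 (dendritic cell, 17) and -0.064 to 0.62 (MHC class II, 17). Means were 0.098 to 0.66 (chemokine, 19), 0.077 to 0.89 (fibroblast, 20), -0.023 to 0.63 (endothelial, 14), 0.10 to 1.70 (keratinocyte, 21), 0.17 to 2.61 (adipocyte, 21), -0.084 to 0.27 (ribosomal protein, 16) and -0.998 to -0.38 (type I interferon response, 21). Each of the 12 libraries, left out, ended a call or moved a mean by over 1.5 times for 1 or more of these lists, and UV2 isotype replicate 1 and parental isotype replicate 3 did so for 13 each. Without UV2 isotype replicate 1 the means were 0.16 (T cell), 0.15 (macrophage), 0.39 (wound) and 0.13 (ribosomal protein) (still past camera) and 0.16 (cytotoxic effector), 0.012 (checkpoint), -0.0073 (NK cell), 0.030 (regulatory T cell), -0.0053 (neutrophil), -0.0022 (dendritic cell), -0.064 (MHC class II), 0.15 (chemokine) and 0.17 (endothelial) (no longer past it). Without parental isotype replicate 3 the means were 0.30 (T cell), 0.36 (cytotoxic effector), 0.28 (checkpoint), 0.21 (NK cell), 0.13 (macrophage) and 0.49 (wound) (still past camera) and 0.15 (regulatory T cell), -0.15 (neutrophil), 0.0061 (dendritic cell), -0.035 (MHC class II), 0.098 (chemokine), 0.17 (adipocyte) and -0.039 (ribosomal protein) (no longer past it). The keratinocyte mean was 0.10 without UV2 anti-PD-1 replicate 3 and did not pass.

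Other splits of the 12 libraries do not exclude chance for the list differences. The real assignment gave 19 lists, the highest other split gave 23, and 37 of 100 splits gave at least 19. For single genes the real count was 0, so that 100 of 100 splits gave at least as many was fixed and decides nothing. The highest other count among the 100 splits was 3057, and what sets the sides of that split apart was not tested.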

How the results depend on the processing

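Covariates and gene-by-gene weights were chosen after seeing the data. Of the comparisons of named genes with an alternative, 9098 kept their side of the threshold, 439 moved past it, 657 moved back, 227 more passed in neither and moved by more than the spread between libraries, and 0 called ones turned direction. The sign also changed in 152 that passed in neither. Of those of list means, 3294 kept their side, 182 moved past, 232 moved back, 1 passed in neither and moved by more than the spread, and 27 past the threshold in either setting turned camera direction. The sign of the mean changed in 283, of which 211 passed in neither. Of 159 called named genes, 121 (no filter) to 159 (library weights) stayed called with no library left out. Leaving out replicate 1, 2 or 3 kept 107, 91 or 1 of 117 (UV2 anti-PD-1) and 73, 103 or 1 of 115 (parental anti-PD-1). For isotype it kept 34, 2 or 15 of 41 (UV2) and 2, 2 or 37 of 42 (parental). A pseudocount of 0.1 gave 5 genes for triple therapy against isotype and 4 against anti-PD-1, list levels of -1.91 for erythrocyte genes in UV2 against parental isotype, 0.18 for keratinocyte genes in parental anti-PD-1 against isotype, -0.58 for regulatory T cell genes in triple therapy against anti-PD-1, and 1.40 and 1.56 for regulatory T cell and dendritic cell genes in UV2 against parental anti-PD-1. No filter gave 82 genes for UV2 against parental isotype and 0 for triple therapy against isotype. Median-of-ratios scaling gave 0 genes for triple therapy against isotype, 1 for UV2 anti-PD-1 against isotype and 11 lists for the interaction, levels of 0.10 (heat shock) and 0.13 (immediate early genes) for triple therapy against isotype, and 1.35 (macrophage), 0.15 (melanocyte lineage), -0.49 (proliferation), 0.16 (p53) and 0.57 (ribosomal protein) for UV2 against parental anti-PD-1. Quantile normalization gave 0 genes for triple therapy against isotype, 0 for UV2 anti-PD-1 against isotype and 11 interaction lists. The fit on the compared groups alone, which leaves fewer samples to estimate the spread, gave 21 genes for UV2 against parental isotype, 0 for triple therapy against isotype and 0 for UV2 anti-PD-1 against isotype, and the replicate block gave 37 for UV2 against parental isotype and 0 for triple therapy against isotype.

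The planned library weights did not converge, with a weight of 73.8 for parental triple therapy replicate 3. They gave 3704 genes for UV2 against parental isotype, 412 for parental anti-PD-1 against isotype, 7576 and 4527 for triple therapy against isotype and anti-PD-1, 2911 for UV2 anti-PD-1 against isotype, 9262 for UV2 against parental anti-PD-1 and 1303 for the interaction, and turned T cell genes in triple therapy against isotype (0.32) and MHC class II genes in triple therapy against anti-PD-1 (0.32). Gene-by-gene weights gave 2053, 1, 3312, 2273, 116 and 8095 genes for the 6 comparisons in the same order and 0.28 and 0.22 for those lists. The muscle covariate gave 0 genes for triple therapy against isotype and 0 for UV2 anti-PD-1 against isotype. The keratinocyte covariate gave 528 genes for UV2 against parental isotype, 5 for triple therapy against isotype and 2225 for UV2 against parental anti-PD-1. It turned dedifferentiated melanoma (0.59), proliferation (0.52), endothelial (0.15), skeletal muscle (-0.091) and hypoxia genes (0.44) in triple therapy against isotype, and Toll-like receptor (0.11), dedifferentiated melanoma (0.49), proliferation (0.55), endothelial (0.15) and hypoxia genes (0.24) against anti-PD-1.

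Leaving out 1 library at a time gave 3 to 458 genes for UV2 against parental isotype, 0 to 257 for triple therapy against isotype, 0 to 195 against anti-PD-1, 0 to 3 for UV2 anti-PD-1 against isotype and 9 to 4074 for UV2 against parental anti-PD-1. The lists past camera numbered 3 to 22 for parental anti-PD-1 against isotype, 16 to 26 for UV2 anti-PD-1 against isotype and 12 to 23 for the interaction. List means in parental anti-PD-1 against isotype ran from -0.16 to 0.25 (NK cell), -0.49 to 0.68 (B and plasma cell), -0.22 to 0.19 (dendritic cell), -0.26 to 0.22 (type I interferon response), 0.21 to 0.82 (MHC class II) and -0.999 to 1.44 (adipocyte). T cell genes ran from -0.34 to 0.26 in triple therapy against isotype and proliferation genes from -0.34 to 0.15 against anti-PD-1. In UV2 anti-PD-1 against isotype the ranges were -0.071 to 0.41 (MHC class I), -0.10 to 0.42 (hypoxia) and -0.18 to 0.056 (ribosomal protein), and for the interaction -0.34 to 0.15 (MHC class I) and -0.084 to 0.15 (ribosomal protein). With 1 library fewer a group rests on 2, and for each of the other changed results above the cause was not tested. The unknown depth leaves open how much of the spread of low values is counting noise.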

Other observations

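Of the tests below, the loss of the Y chromosome and both tests of keratinocyte transcripts were chosen after the result was seen, as was the list of 25 sterol synthesis genes. The genes called between the UV2 and parental lines numbered 176 under isotype and 3586 under anti-PD-1, comparisons that share no library, and overlapped more than independence gives: 94 genes were higher in UV2 under both antibodies (11.4 if independent), 49 were lower in both (9.05 if independent) and 0 had opposite calls. Of the 176 genes called under isotype, 175 had the same sign under anti-PD-1. Across all genes the correlation of the log2 fold changes was 0.773. The anti-PD-1 effects in the parental and UV2 lines, which also share no library, correlated at -0.0311.

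Sterol synthesis genes moved together in UV2 tumors given anti-PD-1. Of the 25 measured, 24 were lower than under isotype, 2 past the test over all genes and 21 adjusted over the list alone, with a median log2 fold change of -1.20 (range -1.75 to 0.10). The camera p of this list was 1.70e-25 and its p 0.00557 with an estimated correlation, but the list was chosen from the pattern and is no independent test. In the parental line the median with anti-PD-1 was -0.00159. Against parental anti-PD-1 tumors, 24 were lower in UV2 and 21 passed over all genes (median -1.81). That difference includes one between the lines: under isotype 22 were lower in UV2 (median -0.51). Triple therapy against isotype gave 20 lower (median -0.26).

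A candidate explanation for the lower sterol genes is a change in the share of leukocytes. With the level of Ptprc, the pan-leukocyte gene, as a covariate their median stayed at -1.02 (quartiles -1.26 and -0.87) against -0.50 for proliferation genes, which argues against this as the whole cause. The sterol list lay lower than genes following the Y-linked sum in parental libraries (difference -0.85), but it was chosen from this comparison. Leaving out 1 library at a time gave medians from -1.38 to -1.04. A general fall of tumor cell transcripts, a response to therapy, a change in the type of leukocyte and differences between single tumors stay open.

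Y-linked transcripts were measured in the parental libraries and nearly absent in UV2, where their sum was at most 0.02 TPM. Dilution of tumor cells in UV2 tumors could lower them. For 346 genes that follow the Y-linked sum in parental libraries, the median ratio of UV2 to parental isotype was 0.775. Their 5th to 95th percentile was 0.314 to 1.23, which argues against dilution if they mark tumor cells. That all 4 measured Y genes were under 0.1 TPM in all 6 UV2 libraries follows from the sum above and is no separate test. A loss of the Y chromosome and silencing of its genes stay open.

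Keratinocyte transcripts in triple therapy libraries could come from sampled skin, a skin response to laser and cream, or melanoma cells switching on wound keratins. Of 4 differentiated keratinocyte genes, Krt1, Krt10 and Krtdap exceeded 1 TPM in all 3 libraries and ranked as Krt14 did. Lor was listed at 0 in replicate 2. Krt10 was at least 1.37 TPM in all 15 libraries, which fixed its pass. The ratio of Krt14 to the Y-linked sum differed 2997-fold between the 3 libraries. The same program in all tumor cells would give a similar ratio. The bound of this test was revised after its value was seen. Tumor cells would need up to 753590 of 1000000 TPM for 5 keratins alone, which is not excluded, so both explanations stay open. The treatment acts on skin, so a biological response and skin taken along with the tumor cannot be told apart here.

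Other splits of the libraries of each comparison number 10, too few for a share under 0.05. For UV2 against parental isotype the real count was 176 genes and the highest other 1 (1 of 10 splits as large), with 20 lists against 21 (2 of 10). For parental anti-PD-1 against isotype it was 9 lists against 18 (8 of 10) and 0 genes against 0 (10 of 10), a share that a real count of 0 fixes and that decides nothing. Triple therapy gave 3 genes against 0 (1 of 10) and 17 lists against 19 (2 of 10) beside isotype, and 14 lists against 17 (5 of 10) beside anti-PD-1. There the 0 genes against 0 (10 of 10) decide nothing either. UV2 against parental anti-PD-1 gave 3586 genes against 1 (1 of 10) and 20 lists against 22 (5 of 10). UV2 anti-PD-1 against isotype gave 26 lists against 24 (1 of 10) and 2 genes against 1812 (3 of 10). The split with 1812 genes set UV2 isotype replicates 1 and 3 and UV2 anti-PD-1 replicate 1 against the other 3 libraries, which points to a structure of the samples other than the antibody.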
